A study of Arabidopsis thaliana with 12 samples.

How the data were processed

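RNA-seq was performed on whole seedlings of Arabidopsis thaliana that had grown for 3 days in the dark. Wild-type plants and a BES1-RNAi line were sampled in the dark or after 1 h of continuous green light at 10 µmol m-2 s-1. BES1 is a transcription factor of the brassinosteroid pathway, and an RNAi line carries a transgene that lowers the transcript of its target by RNA interference. Each of the 4 groups held 3 libraries, 12 in all. Per the labels' protocols, total RNA was extracted with RNAiso Plus and libraries were made with an Illumina TruSeq RNA kit. Sequencing used an Illumina HiSeq instrument. The labels call the libraries replicates and do not say whether they came from separately grown seedlings, so p-values measure the spread between these libraries only.

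The deposited values are FPKM (fragments per kilobase of transcript, relative to the mapped fragments of the library), given per gene and library to 2 decimals. Per the submitters' processing notes, the tools named were Trimmomatic 0.36, HISAT2 2.2.1.0, Cufflinks, TopHat, Bowtie2 and DESeq 1.18.0, with the genome build TAIR10. The notes used here give no role or order for these tools. FPKM values correct for gene length and for the total of each library, and a few abundant RNAs that take a changing share of that total shift every other value. The library type with respect to strand and the treatment of reads that match several loci are not given in the sources used here. Loci with near-identical copies are therefore uncertain. In all 6 wild-type libraries, the ribosomal RNA loci AT2G01020 and AT3G41979 had identical values, as had ATCG00920 and ATCG01210, and AT2G07675 and ATMG00980.

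The tables used here hold a selection of genes. The wild-type libraries list 1287 genes and the BES1-RNAi libraries 1077, with 633 genes in both, 654 in wild type alone and 444 in BES1-RNAi alone, 1731 in all. The filter behind these lists is not given in the sources used here. The mean FPKM of 1080 of the 1287 wild-type genes and 1009 of the 1077 BES1-RNAi genes differed at least 2-fold between dark and light. The order of genes in the tables followed the p-value of the light difference computed here, with a Spearman correlation across genes of 0.865 in wild type and 0.929 in BES1-RNAi. The genes were thus chosen on the light difference in these same libraries. The p-values and the counts of changed genes describe these lists and are not independent evidence, and nothing is said about the rest of the genome. A gene listed for 1 genotype is not shown to behave differently in the other. The BES1/BZR1 family was not analysed here, so the silencing of BES1 was not checked.

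The number of reads per library is unknown. The sums of the listed FPKM ranged from 45053 to 172431 and are not depths. Low values were searched for the steps that whole reads would leave, with gene lengths from the reference annotation. In each library between 7 and 95 of 100 shuffles of the lengths came as close to whole steps as the real lengths, so no reads were recovered and no counting intervals are given. Among libraries of the same group, Spearman correlations across genes, which are not independent replicates, were at least 0.966, and at most 2.10% of the values of any pair were equal. All libraries were counted as separate.

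Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend and without further scaling between libraries. A log2 change is on this scale, which understates the change of genes with low values. Where low values differ between genotypes, it can therefore understate or overstate the difference between the responses. Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested and a threshold of adjusted p under 0.05. Light responses were fitted in the 6 libraries of each genotype. Differences between genotypes in the dark and in green light, and the difference between the light responses (the interaction), were fitted over the 633 shared genes in all 12 libraries, which then share 1 estimate of the spread. No count model was used, since the values are not counts. On data simulated from the real means with 200 changed genes, the tests recovered 85.1% of genes changed by 1 on the log2 scale in wild type, 91.0% in BES1-RNAi, 100% for the dark difference, 98.5% for the green-light difference and 85.1% for the interaction. At a change of 0.5 these shares were 25.4%, 70.1%, 71.6%, 73.1% and 50.7%, and false calls numbered 8, 7, 3, 7 and 6.

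Groups, comparisons, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Named genes are, per comparison, the 8 rising and 8 falling genes with the largest fold among those past the threshold, with no overlap between the groups' libraries and a mean of at least 1 FPKM in the higher group (5 per direction for the interaction), and up to 4 members with the lowest adjusted p of each fixed list with at least 3 measured members. Lists covered brassinosteroid synthesis and signalling, early auxin response, auxin synthesis and transport, light signalling, light-responsive BBX, GATA and GLK transcription factors, photosynthesis, photoprotection, chlorophyll, carotenoid and flavonoid synthesis, the circadian clock, cell wall loosening, gibberellin, ethylene, heat shock, touch and wounding, seed reserves, root markers, stomatal lineage markers and organelle-encoded genes. Lists with at least 5 measured members were tested with fry from limma, which asks whether the members move, on balance, in the same direction and does not compare them with other genes. Its p-values were adjusted over the lists tested in each comparison. List counts are to be read beside those over all genes. In light, 810 of 1287 genes rose in wild type and 792 of 1077 in BES1-RNAi. Of the 633 shared genes, 308 in the dark and 346 in green light were higher in BES1-RNAi. Measured members are those among the genes chosen on the light difference. The lists themselves were larger, with 27 ethylene, 20 chlorophyll, 45 photosynthesis and 39 early auxin response genes. Statements on all or most measured members therefore do not describe whole pathways. Whether list members were listed for the 2 genotypes equally often was tested with an exact McNemar test, adjusted over 18 lists. Gene names came from the reference annotation TAIR10.1, where 1713 of the 1731 loci matched. The remaining 18 are organelle loci and are named by locus. No coordinates were taken from it.

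Alternatives were pseudocounts of 0.1 and 5, a minimum mean of 1 FPKM, median-of-ratios scaling between libraries, limma without trend and with robust moderation, a minimum fold of 2, the replicate number as a block, each library left out in turn and, for the light responses, all 12 libraries in 1 fit. Scaling moved the median log2 change over all genes by -0.74 for the light response in wild type, -1.05 in BES1-RNAi, -0.40 for the dark difference, -0.57 for the green-light difference and -0.16 for the interaction. It centres the listed genes, so a direction after scaling is relative to the median listed gene. On lists chosen for their change, neither scale can be shown to be the right one. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.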

Results

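Transcript levels were measured by RNA-seq in 3-day-old dark-grown seedlings of wild type and of a BES1-RNAi line, before and after 1 h of green light. BES1 promotes the elongation growth that seedlings show in the dark, and the design asks which transcripts respond to green light and whether that response differs when BES1 is targeted. Values are FPKM, given as mean ± SD with n = 3 libraries per group. The wild-type libraries covered 1287 genes and the BES1-RNAi libraries 1077, all selected on their light difference in these same libraries, and sequencing depth is unknown. BES1 itself was not analysed here, so the libraries are named by their labels and the silencing was not checked.

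In wild type, 1 h of green light raised genes of light signalling, pigment synthesis and the circadian clock and lowered most measured genes of auxin response. ELIP1, which encodes an early light-induced protein of the thylakoid membrane, rose from 3.1 ± 0.557 to 337 ± 52.9 FPKM. F3H, a flavanone 3-hydroxylase of flavonoid synthesis, rose from 0.643 ± 0.174 to 74.7 ± 2.94 FPKM, and HY5, a bZIP transcription factor that promotes photomorphogenesis, from 18.7 ± 1.11 to 235 ± 15.3 FPKM. PIL1, a bHLH gene of the phytochrome-interacting family, fell from 48.8 ± 2.95 to 2.51 ± 1.16 FPKM, and ATHB2, a homeobox gene of the shade response, from 94.6 ± 5.15 to 12.1 ± 2.55 FPKM. Of the 1287 genes, 810 rose, 446 fell and 31 did not pass (limma, Benjamini-Hochberg adjusted p under 0.05), and the values of dark and light libraries did not overlap for 1239 genes. Chance gives 10% for unselected genes, which is no reference for genes chosen on this difference.

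Among the other genes with the largest increases, BBX32 rose from 0.0767 ± 0.133 to 42.9 ± 4.04 FPKM, and SIGE, a sigma factor of the plastid RNA polymerase, from 0.880 ± 0.234 to 67.3 ± 4.09 FPKM. The putative potassium transporter AT3G56290 rose from 1.5 ± 0.324 to 66.5 ± 5.23 FPKM. Among the largest decreases, RTFL21 fell from 68.6 ± 6.92 to 4.30 ± 0.323 FPKM and BT2 from 119.7 ± 17.3 to 12.8 ± 4.24 FPKM. The cytochrome P450 genes CYP71A12 and CYP82C2 fell with a wide spread in the dark, from 59.8 ± 39.4 to 3.15 ± 3.13 and from 26.1 ± 18.4 to 2.24 ± 2.25 FPKM. The non-coding RNA AT1G09103 fell from 30.7 ± 6.51 to 2.38 ± 2.24 FPKM, and AT2G07805 from 8.05 ± 2.66 to 0.197 ± 0.341 FPKM.

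Of 17 measured genes of photoreceptors and light signalling, 12 rose and 5 fell. PKS1, a phytochrome kinase substrate, rose from 10.5 ± 1.02 to 117 ± 4.50 FPKM, RUP2, a repressor of UV-B signalling, from 2.08 ± 0.260 to 40.6 ± 3.21 FPKM, and SPA1, a partner of the ubiquitin ligase COP1, from 7.19 ± 0.637 to 64.0 ± 5.77 FPKM. The 5 that fell were PIL1, ATHB2, FHY1, FHL and PHOT1, and the list rose on balance (fry, adjusted p = 1.1e-05). Of 11 light-responsive BBX, GATA and GLK transcription factors, 9 rose and BBX23 and GATA2 fell (adjusted p = 1.1e-05). GLK2, which activates chloroplast genes, rose from 29.4 ± 0.703 to 222 ± 5.04 FPKM, and BBX25 from 1.11 ± 0.356 to 45.3 ± 6.72 FPKM.

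All 11 measured nuclear photosynthesis genes rose (fry, adjusted p = 0.0020). LHCB1.1, a light-harvesting chlorophyll-binding protein, rose from 14.3 ± 2.47 to 231 ± 80.4 FPKM and LHCB2.1 from 65.3 ± 5.36 to 341 ± 81.9 FPKM. After scaling by the median listed gene, 4 of the 11 rose and 7 did not pass, with an adjusted p of 0.075 for the list, which ranged from 3.6e-05 to 0.075 over its alternatives. All 6 photoprotection genes rose (adjusted p = 3.0e-05), with ELIP2 going from 3.88 ± 0.491 to 159.7 ± 60.1 FPKM. All 4 chlorophyll genes rose, with CHLH, a subunit of magnesium chelatase, going from 52.2 ± 5.70 to 158 ± 9.85 FPKM and GUN4 from 37.3 ± 1.69 to 138 ± 22.0 FPKM. All 3 carotenoid genes rose, among them PSY, phytoene synthase, from 30.2 ± 2.63 to 79.2 ± 12.4 FPKM. After scaling, 3 photoprotection, 3 chlorophyll and 2 carotenoid genes still rose, and the values of CRD1 and BCH1 turned below 0 without passing.

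All 9 flavonoid and phenylpropanoid genes rose (fry, adjusted p = 8.2e-05). CHI, chalcone isomerase, rose from 4.13 ± 0.750 to 15.6 ± 2.39 FPKM and the regulator MYB12 from 0.0900 ± 0.0900 to 1.81 ± 0.153 FPKM. All 12 clock genes rose (adjusted p = 1.1e-05). The pseudo-response regulator PRR9 rose from 1.92 ± 0.379 to 74.1 ± 7.33 FPKM, and the morning-phased CCA1 from 17.8 ± 1.60 to 149.8 ± 12.4 FPKM. After scaling, 8 flavonoid and 10 clock genes still rose, and none fell.

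Of 10 early auxin response genes, 9 fell and SAUR14 rose (fry, adjusted p = 2.6e-05). IAA29, an Aux/IAA repressor gene, fell from 36.4 ± 1.49 to 4.36 ± 0.262 FPKM, IAA19 from 345 ± 12.8 to 91.6 ± 8.98 FPKM, and GH3.3 from 33.8 ± 0.796 to 11.2 ± 0.582 FPKM. The rise of SAUR14 did not pass after scaling. The 3 brassinosteroid signalling genes fell: PRE6 from 149.8 ± 14.5 to 38.7 ± 3.18 FPKM, and IBH1 and BEE3 by less. PRE6 is a growth-promoting bHLH protein and IBH1 an antagonist of such proteins, so the members of this list act in opposite directions on growth. BAS1, which inactivates brassinosteroids, fell by 1.37 on the log2 scale and was the only measured gene of brassinosteroid synthesis and inactivation.

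Of 7 cell wall genes, 4 xyloglucan endotransglucosylase genes fell and 3 expansin genes rose (median log2 change -1.22, mean -0.37, fry direction down, adjusted p = 0.0027). XTH15 fell from 1340 ± 142 to 267 ± 25.9 FPKM and EXPA1 rose from 33.1 ± 1.31 to 85.3 ± 3.37 FPKM. Of 6 gibberellin genes, 4 rose and 2 fell (adjusted p = 8.2e-05, and 0.052 after scaling, the highest of its alternatives, which began at 6.0e-08). Those that rose included GA2OX1, a gibberellin-inactivating oxidase, from 0.913 ± 0.396 to 51.6 ± 4.63 FPKM, and GA3OX2, a gibberellin-activating oxidase, from 0.457 ± 0.284 to 6.22 ± 1.31 FPKM. GAI, a DELLA repressor of growth, fell from 45.6 ± 1.42 to 18.0 ± 2.45 FPKM. Of 3 ethylene genes, ACS8 and HLS1 fell and ERF11 rose, the last not after scaling.

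All 9 heat shock genes rose (fry, adjusted p = 0.00042), with HSP70 going from 66.8 ± 8.27 to 198 ± 20.3 FPKM and the heat shock factor HSFA2 from 3.56 ± 0.645 to 17.57 ± 3.28 FPKM. After scaling, 2 of the 9 rose and 7 did not pass, with adjusted p = 0.029 for the list, the highest of its alternatives, which began at 0.00041. The 3 measured touch and wounding genes were the cold-response regulators CBF1, CBF2 and CBF3, and all rose, CBF2 from 1.97 ± 0.361 to 10.98 ± 2.39 FPKM. The seed storage gene SESA5 rose by 0.87 on the log2 scale and the root hair gene RSL4 by 0.60, both not after scaling, and COBL9 had a log2 change of 0.47 without passing. Of 17 organelle-encoded genes, 9 rose and 8 did not pass, with 6 rising when adjusted over the list alone (fry, adjusted p = 0.11), and none passed after scaling. Among the 9 were ATCG00920 and ATCG01210, with identical values, and ATCG00950 and ATCG01180, with log2 changes of 1.376 and 1.374. Each of these pairs may count 1 signal more than once. The ribosomal RNA locus AT2G01020 read 8038, 4138 and 8010 FPKM in the dark libraries and 19426, 33636 and 52910 FPKM in the light libraries. These values moved with the same groups as every list above. For each other list of this comparison, the counts adjusted over the list alone equalled those over all genes.

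Light and dark libraries thus differed with the scale used: 810 genes rose and 446 fell without scaling, and 359 rose and 447 fell after it. The log2 values of all lists are to be read beside a shift of -0.74 that scaling made in the median gene.

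**Figure D1:**
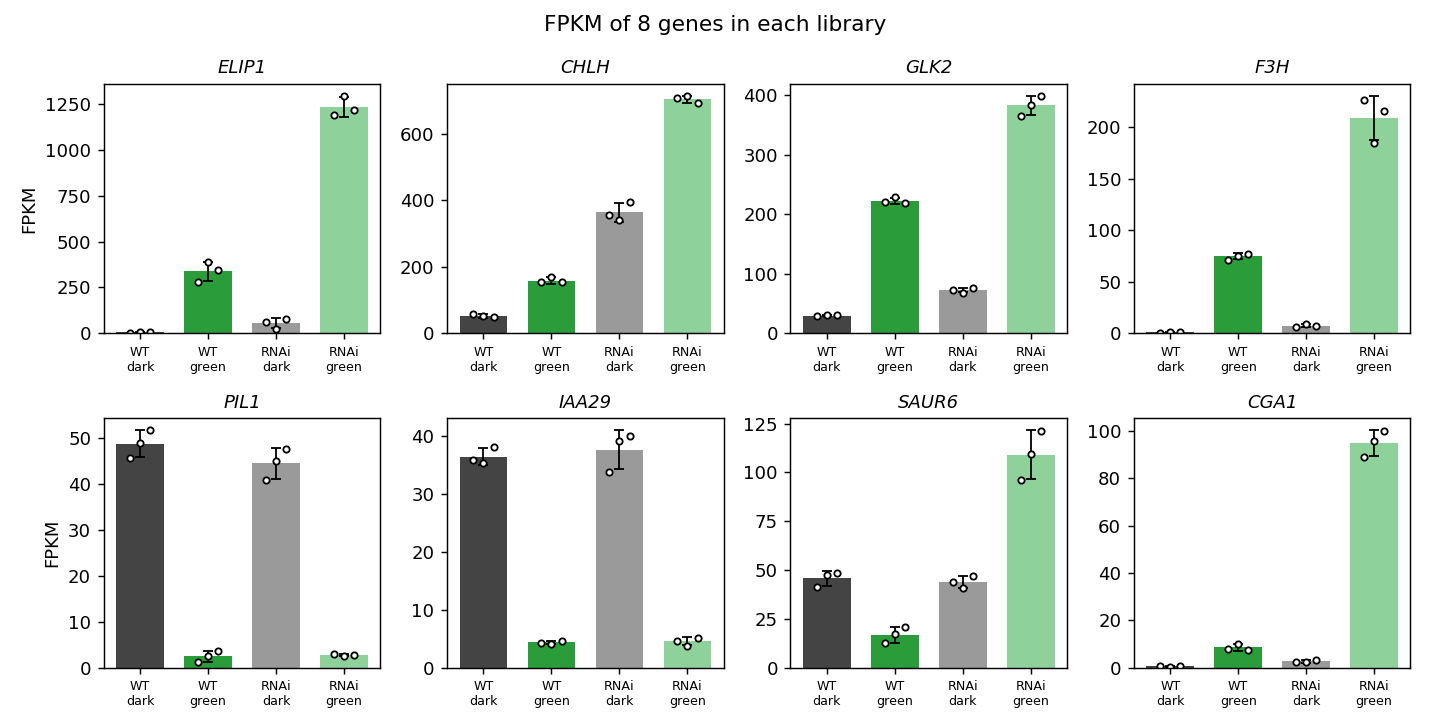
FPKM of 8 genes in the 4 groups on linear axes that start at 0; bars are means, error bars SD and points the 3 libraries of each group. ELIP1 reached 337 FPKM in wild-type light and 1236 FPKM in BES1-RNAi light, PIL1 and IAA29 fell in both genotypes, SAUR6 fell in wild type and rose in BES1-RNAi, and after scaling CHLH no longer rose in BES1-RNAi.

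In BES1-RNAi, green light raised genes of flavonoid synthesis and the clock and lowered all 5 measured ethylene genes of a list of 27. Without scaling it also raised most measured genes of light signalling and all 4 measured chlorophyll genes of a list of 20. After scaling, 1 of these 4 rose. ELIP2 rose from 29.5 ± 4.81 to 890.1 ± 50.5 FPKM, F3H from 7.07 ± 1.47 to 209 ± 21.7 FPKM, and CGA1, a cytokinin-responsive GATA factor that promotes chloroplast development, from 2.76 ± 0.613 to 94.9 ± 5.41 FPKM. BBX23, a B-box transcription factor, fell from 40.3 ± 2.1 to 1.25 ± 0.0666 FPKM and PIL1 from 44.5 ± 3.34 to 2.84 ± 0.265 FPKM. Of the 1077 genes, 792 rose, 281 fell and 4 did not pass (limma, Benjamini-Hochberg adjusted p under 0.05), and dark and light values did not overlap for 1065 genes, where the 10% that chance gives for unselected genes is again no reference. The 4 were CYP71B11, AT1G62760, AT2G18340 and AT3G03815, with log2 changes of 0.65, -0.54, 0.86 and 1.14. After scaling, 314 genes rose and 294 fell.

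Other large increases were those of ABCI21, from 16.1 ± 1.76 to 443 ± 20.8 FPKM, BBX32, from 0.267 ± 0.118 to 46.7 ± 11.1 FPKM, AT3G56290, from 4.86 ± 0.225 to 153 ± 4.70 FPKM, and the thionin gene THI2.2, from 1.11 ± 0.871 to 42.2 ± 7.57 FPKM. Other large decreases were those of AT5G57760, from 215 ± 10.8 to 10.5 ± 1.62 FPKM, the growth-regulating factor GRF7, from 104 ± 9.09 to 10.0 ± 2.04 FPKM, FLP1, from 257 ± 48.0 to 28.3 ± 8.36 FPKM, and the homeobox gene HB52, from 63.7 ± 7.18 to 6.56 ± 2.03 FPKM. The zinc finger gene AT5G44260 fell from 99.6 ± 3.51 to 9.86 ± 3.01 FPKM and RTFL21 from 57.5 ± 6.81 to 4.74 ± 1.89 FPKM.

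Of 17 light signalling genes, 13 rose and 4 fell (fry, adjusted p = 4.5e-05). RUP2 rose from 4.61 ± 0.507 to 109 ± 1.86 FPKM and SPA1 from 14.3 ± 1.1 to 105 ± 3.59 FPKM, while FHY1, needed for nuclear import of phytochrome A, fell from 101 ± 4.79 to 17.2 ± 0.995 FPKM. Of 12 BBX, GATA and GLK factors, 9 rose and BBX23, GATA2 and GATA4 fell (adjusted p = 4.8e-05). After scaling, the list test no longer passed for light signalling (adjusted p = 0.42) or for these factors (adjusted p = 0.70), each the highest of its alternatives, which began at 4.5e-09, although 10 and 9 members still rose. All 12 flavonoid genes rose (adjusted p = 4.5e-05), with PAP1, a regulator of anthocyanin synthesis, going from 0.240 ± 0.0700 to 8.21 ± 0.926 FPKM and 4CL3 from 1.73 ± 0.357 to 12.2 ± 0.0850 FPKM. After scaling 10 rose, 1 fell and 1 did not pass. All 10 clock genes rose (adjusted p = 4.5e-05), with PRR9 going from 4.64 ± 0.490 to 106 ± 13.1 FPKM and LHY from 49.8 ± 2.40 to 195 ± 5.04 FPKM, and after scaling 8 rose and 2 did not pass.

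All 5 photoprotection genes (fry, adjusted p = 5.1e-05), 4 chlorophyll genes and 3 carotenoid genes rose. GUN4 rose from 120.2 ± 3.07 to 382 ± 20.5 FPKM, CHLH from 363 ± 28.7 to 704 ± 10.98 FPKM and PSY from 86.0 ± 3.2 to 270.3 ± 9.18 FPKM. After scaling, 3 photoprotection, 1 chlorophyll and 2 carotenoid genes rose, and the values of CHLH, CAO, HEMA1 and PSBS turned below 0 without passing. Of 3 photosynthesis genes, RBCS1B and LHCB2.2 rose and LHCB1.4 fell, from 625 ± 213 to 255 ± 26.6 FPKM. After scaling, the values of RBCS1B and LHCB2.2 turned below 0 without passing. Of 5 early auxin response genes, 3 fell and SAUR14 and IAA5 rose (adjusted p = 0.00016), with SAUR14 going from 19.9 ± 1.66 to 155 ± 24.1 FPKM and IAA20 from 62.0 ± 4.85 to 18.6 ± 0.187 FPKM. After scaling 1 rose, 3 fell and 1 did not pass. PRE6 and BEE3, the measured brassinosteroid signalling genes, fell by 1.33 and 2.78 on the log2 scale.

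All 5 measured ethylene genes fell (fry, adjusted p = 4.2e-05). They were EBF2, from 94.5 ± 6.87 to 27.3 ± 1.51 FPKM, HLS1, which maintains the apical hook, from 24.2 ± 1.23 to 5.16 ± 0.197 FPKM, the receptor genes ETR2 and ERS2, and ACO4 of ethylene synthesis. Of 5 gibberellin genes, 4 rose and GAI fell (adjusted p = 9.7e-05, and 0.057 after scaling, the highest of its alternatives, which began at 9.2e-08). GA2OX1 rose from 1.09 ± 0.456 to 30.2 ± 1.47 FPKM. Of 4 cell wall genes, XTH15 fell from 1225 ± 168 to 160.4 ± 15 FPKM and EXPA1, EXPA10 and XTH22 rose. After scaling, 1 rose, 1 fell and 2 did not pass, with XTH22 below 0. All 4 heat shock genes rose, with HSP70 going from 41.6 ± 8.23 to 216 ± 8.77 FPKM, and 3 did so after scaling. CBF3 and the plastid gene ATCG00800 rose by 0.85 and 1.19 on the log2 scale, both not after scaling. The ribosomal RNA locus AT2G01020 rose from 2396 ± 954 to 6093 ± 1062 FPKM. Counts adjusted over each list alone equalled those over all genes.

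**Figure D2:**
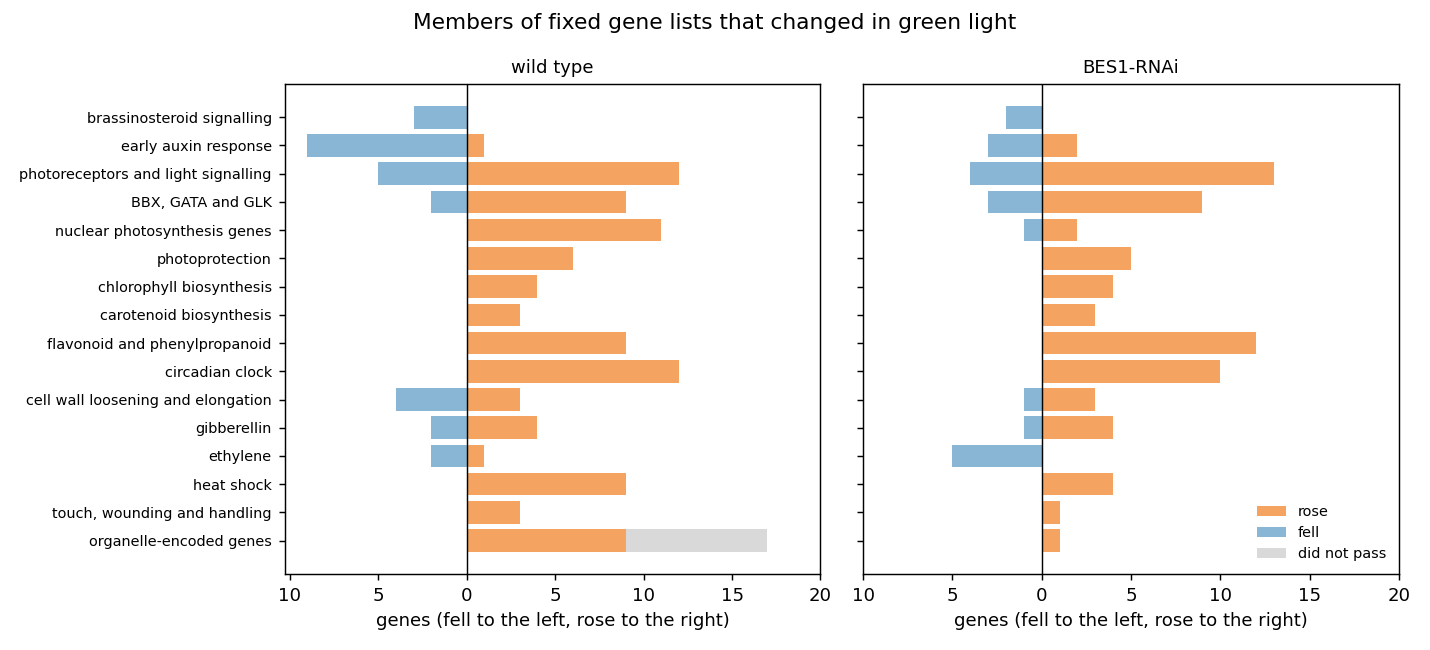
Members of the fixed gene lists that rose, fell or did not pass in green light in wild type and in BES1-RNAi, as counts of genes along the horizontal axis without scaling between libraries. All 11 nuclear photosynthesis genes and all 9 heat shock genes rose in wild type, where 4 and 2 did so after scaling, and in BES1-RNAi the values of chlorophyll and photosynthesis genes turned in part below 0 after scaling.

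Of the 633 genes listed for both genotypes, 628 passed in the same direction in both, 511 rising and 117 falling. Independent lists with the same numbers of calls would share 417 rising and 22.0 falling genes, and since the lists were chosen on the light difference the overlap is not independent evidence. Across these genes, which are not independent replicates, the log2 changes had a Pearson r of 0.928 and a Spearman rho of 0.796. The median change of the rising genes was 1.3 in wild type and 1.44 in BES1-RNAi, and that of the falling genes -1.58 and -1.44. SAUR6, of the SAUR auxin-responsive family, fell in wild type and rose in BES1-RNAi, with log2 changes of -1.40 and 1.29, and PHI-1, of a phosphate-responsive family, did so with -1.14 and 1.02. The remaining 3 genes passed in 1 genotype. CYP71B11 rose in wild type, and AT2G31751 and RPP4, a disease resistance gene, rose in BES1-RNAi. The organelle-encoded list had 17 members in the wild-type table and 1 in the BES1-RNAi table (exact McNemar test, p = 0.00014, adjusted p = 0.0026). That test treats the loci as independent, but the 17 organelle-encoded genes moved together within wild-type groups with a median pairwise correlation of 0.895 over 6 libraries, so this assumption was not met. By the same exact McNemar test, photosynthesis genes numbered 11 and 3 (adjusted p = 0.19) and heat shock genes 9 and 4 (adjusted p = 0.38), and no other list passed.

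**Figure D3:**
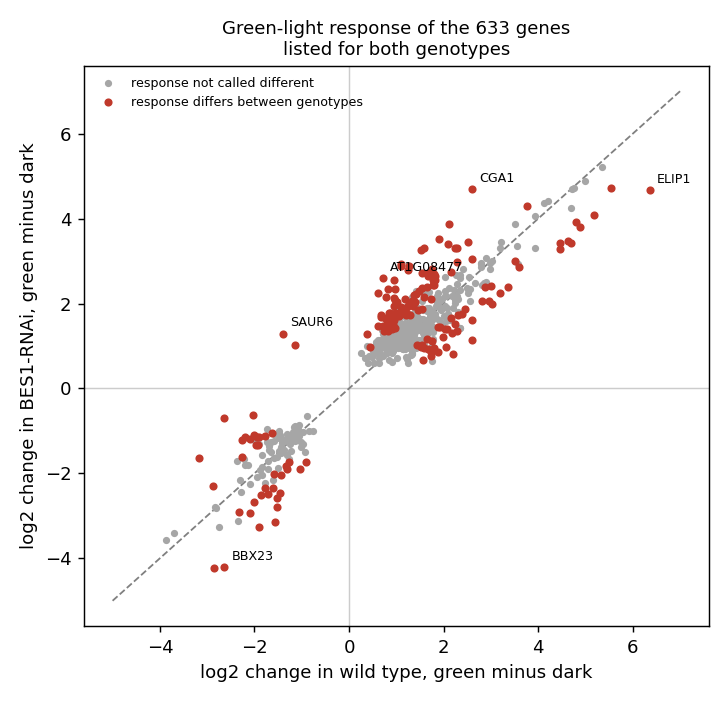
Log2 change in green light of the 633 shared genes in wild type (horizontal) and BES1-RNAi (vertical), with 1 point per gene and the dashed line where both are equal. The 179 red points are genes whose response differed between genotypes, and SAUR6 is among the 2 genes that fell in wild type and rose in BES1-RNAi.

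In the dark, most measured genes of pigment synthesis and photoprotection were higher in BES1-RNAi than in wild type before any light was given. Only genes listed for their light difference in both genotypes could be compared. These were 3 of 20 chlorophyll, 3 of 9 carotenoid and 5 of 8 photoprotection genes. CHLH stood at 363 ± 28.7 FPKM in BES1-RNAi against 52.2 ± 5.70 in wild type, ELIP1 at 53.1 ± 27.9 against 3.1 ± 0.557, and CHS, chalcone synthase, at 16.4 ± 6.59 against 1.88 ± 0.330. The cold- and drought-induced genes KIN1 and KIN2 stood at 34.9 ± 5.09 against 0.990 ± 0.951 and at 89.0 ± 17.37 against 12.8 ± 3.99 FPKM. MIOX2, a myo-inositol oxygenase, was lower at 34.6 ± 1.64 against 204 ± 8.66 FPKM, and the chaperone gene HSP90.1 at 12.3 ± 2.37 against 41.5 ± 2.33 FPKM. Of the 633 shared genes, 308 were higher, 100 lower and 225 did not pass (limma, Benjamini-Hochberg adjusted p under 0.05), and the values of the genotypes did not overlap for 437. The 10% that chance gives for 1 unselected gene is no reference here. The genes were chosen in these same libraries, and a shift between libraries moves many of them at once. After scaling, 198 were higher and 216 lower. The ribosomal RNA locus AT2G01020 differed between the same groups, at 2396 ± 954 FPKM in BES1-RNAi against 6729 ± 2244 in wild type.

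Other genes with large differences were AT1G80130, at 11.3 ± 1.51 against 0.993 ± 0.196 FPKM, and the light-harvesting gene LHCB2.2, at 349.9 ± 92.2 against 58.8 ± 6.23 FPKM. Lower in BES1-RNAi were AT5G38710, at 2.34 ± 0.200 against 26.3 ± 3.59 FPKM, AT2G04500, at 1.33 ± 0.367 against 10.0 ± 0.437 FPKM, AT5G23350, at 7.85 ± 0.888 against 30.0 ± 4.07 FPKM, the defence-related WRKY70, at 4.03 ± 0.943 against 15.5 ± 3.82 FPKM, and RTFL13, at 1.87 ± 0.330 against 7.82 ± 0.716 FPKM.

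All 5 photoprotection genes (fry, adjusted p = 3.1e-06), all 3 chlorophyll genes, all 3 carotenoid genes and both photosynthesis genes measured were higher in BES1-RNAi. CAO stood at 112 ± 11 against 27.2 ± 0.846 FPKM, PSY at 86.0 ± 3.2 against 30.2 ± 2.63 FPKM and PSBS, a photosystem II protein of heat dissipation, at 638 ± 7.56 against 258 ± 24.5 FPKM. After scaling 4, 3, 3 and 2 of them were higher. Of 9 flavonoid genes, 6 were higher and 3 did not pass, with and without scaling (adjusted p = 4.3e-05). Of 10 BBX, GATA and GLK factors, 6 were higher, BBX31 was lower and 3 did not pass (adjusted p = 3.1e-06), with GLK2 at 71.9 ± 3.75 against 29.4 ± 0.703 FPKM and BBX23 at 40.3 ± 2.1 against 8.81 ± 3.34 FPKM. Of 16 light signalling genes, 9 were higher, RUP1 and ATHB2 were lower and 5 did not pass, with HYH, a homologue of HY5, at 19.9 ± 2.26 against 3.32 ± 0.0954 FPKM. Of 10 clock genes, 8 were higher and RVE1 and RVE8 lower, with CCA1 at 42.1 ± 2.44 against 17.8 ± 1.60 FPKM. After scaling, 6 light signalling genes were higher, 5 lower and 5 did not pass. Of the BBX, GATA and GLK factors, 5 were then higher and 2 lower, and of the clock genes 5 higher and 2 lower. The light signalling and clock lists were higher on balance (adjusted p = 2.8e-05 each), which was lost after scaling (adjusted p = 0.48 and 0.15, the highest of their alternatives, which began at 6.9e-06 and 1.4e-05).

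Of 4 heat shock genes, HSP90.1, HSP101 and HSP70 were lower in BES1-RNAi, the last at 41.6 ± 8.23 against 66.8 ± 8.27 FPKM, and HSFA2 did not pass at 4.36 ± 2.02 against 3.56 ± 0.645 FPKM. Without the second dark library of BES1-RNAi, HSFA2 passed with a log2 difference of 0.51. Of 3 auxin response genes, IAA19 was lower at 265 ± 33.5 against 345 ± 12.8 FPKM, and SAUR14 and IAA29 did not pass, while after scaling all 3 were lower. Of 3 cell wall genes, EXPA1 and EXPA10 were higher, EXPA1 at 66.3 ± 6.38 against 33.1 ± 1.31 FPKM, and XTH15 did not pass at 1225 ± 168 against 1340 ± 142 FPKM, being lower after scaling. Of 5 gibberellin genes, GA2OX2 was lower and 4 did not pass (adjusted p = 0.091). The gibberellin list passed, downwards, after scaling (adjusted p = 0.00014, with 4 genes lower) with a pseudocount of 0.1 (adjusted p = 0.030) and without the first green-light library of BES1-RNAi (adjusted p = 0.043), in a range of 0.00014 to 0.26 over its alternatives. PRE6 was lower and BEE3 did not pass, HLS1 was higher by 0.39 on the log2 scale, though not after scaling, and CBF3 did not pass.

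Genes that rose in light in both genotypes were higher in BES1-RNAi darkness in 271 of 511 cases and lower in 65, with a median log2 difference of 0.43. Genes that fell in both were higher in 36 and lower in 34 of 117 cases, with a median of 0.03. The dark difference and the wild-type light response share the wild-type dark libraries. Their log2 values had a Pearson r of 0.309 across the 633 genes, against 0.502 simulated with no effects and 0.0515 simulated with the light effect alone. They had the same sign in 70.0% of genes, against 66.8% and 49.6%. The values simulated with no effects follow from the shared term and are no reference for genes chosen for a light effect. The covariance was 0.386, against 0.0151 simulated with no effects and 0.0137 simulated with the light effect alone. Independent lists would share 249 genes that rose in wild type and were higher in the dark, where 271 did, and 18.8 that fell and were lower, where 35 did. With 3 shared libraries they could not be divided into separate sets of at least 2, so part of any excess may come from the shared libraries.

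In green light, most measured members of the same pigment and photoprotection lists were higher in BES1-RNAi. CGA1 stood at 94.9 ± 5.41 FPKM in BES1-RNAi against 8.59 ± 1.41 in wild type, CHLH at 704 ± 10.98 against 158 ± 9.85, and ELIP2 at 890.1 ± 50.5 against 159.7 ± 60.1. SAUR6 stood at 109 ± 12.6 against 17.0 ± 4.08 FPKM and KIN1 at 92.3 ± 34.3 against 5.79 ± 2.91 FPKM. GolS3, a galactinol synthase, was lower at 17.7 ± 1.06 against 68.0 ± 13.3 FPKM, and MIOX2 at 15.2 ± 1.16 against 53.3 ± 11.4 FPKM. Of the 633 genes, 346 were higher, 101 lower and 186 did not pass (limma, Benjamini-Hochberg adjusted p under 0.05), and the genotypes did not overlap for 467, where 10% is again no reference. After scaling, 198 were higher and 247 lower.

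Also higher were the non-coding RNA AT1G08477, at 282 ± 19.8 against 29.8 ± 5.68 FPKM, AT1G26761, at 19.7 ± 1.12 against 1.27 ± 0.675 FPKM, the pectin lyase-like gene AT1G60590, at 26.3 ± 3.44 against 2.99 ± 0.905 FPKM, CYP96A12, at 18.0 ± 1.81 against 1.90 ± 0.483 FPKM, and AT2G03750, at 64.3 ± 6.50 against 9.61 ± 0.971 FPKM. The ribosomal RNA loci AT2G01020 and AT3G41979 had the largest negative difference, at 6093 ± 1062 against 35324 ± 16806 FPKM. The thioredoxin-family gene AT4G33040, AT4G17670, WRKY70 and IAMT1, which methylates auxin, were lower by at least 2-fold, IAMT1 at 4.29 ± 0.510 against 13.6 ± 2.64 FPKM.

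All 5 photoprotection genes (fry, adjusted p = 6.2e-06), 3 chlorophyll, 3 carotenoid and 2 photosynthesis genes were higher in BES1-RNAi in green light, with and without scaling. BCH2, a beta-carotene hydroxylase, stood at 61.4 ± 2.75 against 14.3 ± 2.59 FPKM and ZEP, zeaxanthin epoxidase, at 132 ± 6.45 against 68.2 ± 3.2 FPKM. Of 9 flavonoid genes, 8 were higher and 1 did not pass (adjusted p = 6.2e-06), and 7 were higher after scaling. CHS stood at 119.8 ± 8.59 against 20.1 ± 9.95 FPKM and PAP1 at 8.21 ± 0.926 against 1.47 ± 0.267 FPKM. Of 16 light signalling genes, 7 were higher, PKS1 and RUP1 lower and 7 did not pass, with HYH at 167 ± 19.7 against 48.4 ± 7.69 FPKM and PKS1 at 58.4 ± 1.48 against 117 ± 4.50 FPKM. Of 10 BBX, GATA and GLK factors, 5 were higher, BBX30 and GATA2 lower and 3 did not pass. Of 10 clock genes, 6 were higher, RVE1 and RVE7 lower and 2 did not pass, with LHY at 195 ± 5.04 against 114 ± 1.65 FPKM. These 3 lists were higher on balance without scaling (adjusted p = 2.9e-05, 1.2e-05 and 0.0039). Their median log2 differences of 0.20, 0.40 and 0.39 lay below the median of 0.46 over all 633 genes, of which 346 were higher. They were thus not raised beyond the listed genes as a whole. After scaling, light signalling and clock genes were lower on balance (adjusted p = 0.0072 and 0.00098) and the BBX, GATA and GLK list did not pass (adjusted p = 0.15). Over their alternatives the adjusted p ranged from 9.2e-06 to 0.0072, from 0.00098 to 0.012 and from 5.5e-06 to 0.15. After scaling, 5 clock genes were lower and none higher, and LHY, LNK1, LNK2 and GLK2 no longer passed. Of the light signalling genes, 5 were then higher and 7 lower, and of the BBX, GATA and GLK factors 2 higher and 4 lower.

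Of 5 gibberellin genes, GA3OX2, GA2OX1 and GA2OX8 were lower, GAI higher and GA2OX2 did not pass (fry direction down, adjusted p = 0.0039). GA3OX2 stood at 3.13 ± 0.891 against 6.22 ± 1.31 FPKM. After scaling, 4 were lower, and GAI turned below 0. Of 4 heat shock genes, HSP90.1, at 48.6 ± 4.36 against 89.8 ± 6.50 FPKM, and HSP101 were lower, and HSP70 and HSFA2 did not pass. After scaling, HSP70 was lower as well. Without the second dark library of BES1-RNAi, HSFA2 passed with a log2 difference of 0.43, and over all libraries it passed with a pseudocount of 5 (0.36). Of 3 auxin response genes, SAUR14 and IAA19 were higher and IAA29 did not pass, with SAUR14 at 155 ± 24.1 against 47.9 ± 7.57 FPKM and IAA19 at 119 ± 5.95 against 91.6 ± 8.98 FPKM. After scaling, IAA19 and IAA29 were lower. EXPA1 and EXPA10 were higher and XTH15 lower, at 160.4 ± 15 against 267 ± 25.9 FPKM. BEE3 and CBF3 were lower, and PRE6 and HLS1 did not pass, both being lower after scaling. In each list of the 2 genotype differences, counts adjusted over the list alone equalled those over all genes.

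**Figure D4:**
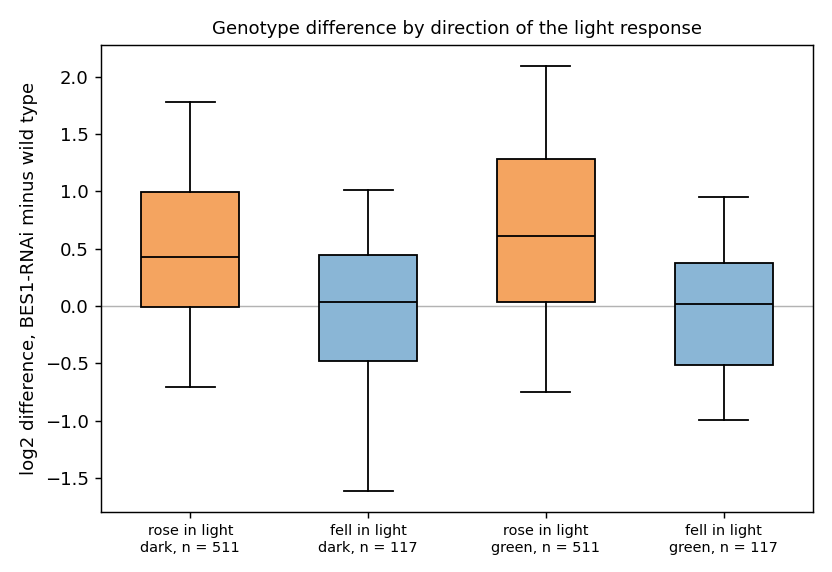
Log2 difference between BES1-RNAi and wild type, in the dark and in green light, of the 511 genes that rose and the 117 genes that fell in both genotypes; boxes give the quartiles with the median, whiskers the central part of the genes, without scaling between libraries. The medians of the rising genes were 0.43 and 0.61 and those of the falling genes 0.03 and 0.02, and scaling lowers each difference by about the shift of the median gene, -0.40 in the dark and -0.57 in light.

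The size of the light response differed between genotypes for 179 of the 633 genes. SAUR6 went from 45.8 ± 3.70 to 17.0 ± 4.08 FPKM in wild type and from 43.8 ± 3.00 to 109 ± 12.6 FPKM in BES1-RNAi, and PHI-1 from 7.94 ± 1.63 to 3.24 ± 1.77 and from 0.887 ± 0.471 to 2.88 ± 1.35 FPKM. CGA1 went from 0.567 ± 0.101 to 8.59 ± 1.41 FPKM in wild type and from 2.76 ± 0.613 to 94.9 ± 5.41 FPKM in BES1-RNAi. RVE7, a clock-related MYB gene, went from 26.3 ± 1.52 to 164 ± 15.1 and from 53.1 ± 9.62 to 118 ± 8.34 FPKM, a smaller rise in BES1-RNAi. In 112 genes the change was more positive in BES1-RNAi and in 67 more negative, and 454 did not pass (limma interaction, Benjamini-Hochberg adjusted p under 0.05). After scaling these numbers were 60 and 95.

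The interaction log2 values, BES1-RNAi response minus wild-type response, were 1.88 for AT1G08477 and 1.95 for AT5G38710, and -1.69 for ELIP1, -1.60 for FLP1, -1.56 for BBX23 and -1.38 for SAUR35. ELIP1 rose less on the log scale in BES1-RNAi, where its dark level was higher, and did not pass with a pseudocount of 5 (log2 -0.84). Of 10 BBX, GATA and GLK factors, 6 had a more negative and CGA1 a more positive change, with BBX25 at -1.02, which did not pass with a pseudocount of 5, and GLK2 at -0.48. The list test did not pass (fry, adjusted p = 0.10), though it did after scaling (0.0024), with the replicate block (0.019) and without the third green-light library of BES1-RNAi (0.031), in a range of 0.0024 to 0.41 over its alternatives. Of 10 clock genes, 4 had a more negative and RVE8 a more positive change, 7 and 2 when adjusted over the list alone, with CCA1 at -0.60, and after scaling 7 had a more negative change and none a more positive one. Its list test gave adjusted p = 0.065, and passed after scaling (0.0024), with the replicate block (0.019), with a pseudocount of 0.1 (0.042) and without the second green-light library of wild type (0.020), the second dark library (0.029) or the third green-light library (0.018) of BES1-RNAi, in a range of 0.0024 to 0.18.

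Of 16 light signalling genes, 3 had a more positive and 4 a more negative change, 5 and 4 when adjusted over the list alone, and 0 and 5 after scaling. PKS1 had an interaction of -0.98, FHY1 of -0.78 and HY5, going from 34.1 ± 5.75 to 254 ± 19.1 FPKM in BES1-RNAi, of -0.72. The list had adjusted p = 0.90, and 0.038 downwards after scaling, the lowest of its alternatives, which ended at 0.97. Of 9 flavonoid genes, PAP1 at 1.62 and CHIL had a more positive and F3H at -0.82 a more negative change. F3H turned to 0.33 with a pseudocount of 5, PAP1 and CHIL did not pass with a pseudocount of 0.1, and CHIL did not pass after scaling. The flavonoid list had adjusted p = 0.10, and passed with a pseudocount of 5 (0.0047) and without the second green-light library of wild type (0.013), in a range of 0.0047 to 0.79. Chlorophyll genes CHLH, at -0.63, and CAO, at -0.55, rose less on the log scale in BES1-RNAi, where their dark levels were higher, and GUN4 did not pass. Of 3 carotenoid genes, BCH1, at 0.55, had a more positive change, though not after scaling. SAUR14, at 1.79, and IAA19, at 0.76, had more positive changes, as had HSP90.1, at 0.82, and HSP70, at 0.81. GA2OX1 had a more negative change, at -0.87, though not with a pseudocount of 0.1, and 4 other gibberellin genes did not pass, of which GA2OX8 (-0.37) and GA3OX2 (-0.39) passed with a pseudocount of 5 (list adjusted p = 0.31, and 0.038 after scaling, the lowest of its alternatives, which ended at 0.79). Of 5 photoprotection genes, ELIP1 had a more negative change and 4 did not pass (adjusted p = 0.89, range 0.069 to 0.99). LHCB2.2 at -1.06, HLS1 at -0.60, CBF3 at -0.88 and BEE3 at -1.26 had more negative changes and PRE6, at 0.59, a more positive change, of which that of BEE3 did not pass after scaling. With a pseudocount of 1, no block and no scaling, none of the 6 lists tested passed over all libraries.

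Several interaction calls changed when 1 library was left out. Of 3 cell wall genes, XTH15 had an interaction of -0.60 and EXPA1 and EXPA10 did not pass. With log2 values of -0.51 to -0.57, XTH15 no longer passed without wild-type dark library 2 (adjusted p = 0.066), wild-type green-light library 1 (0.054) or 3 (0.069), BES1-RNAi dark library 1 (0.056) or 3 (0.064), or BES1-RNAi green-light library 3 (0.083). The clock genes ELF4, at -0.89, and RVE1, at -0.50, are among the 4 with a more negative change. With log2 values of -0.73 to -0.89, ELF4 no longer passed without wild-type dark library 1 (adjusted p = 0.070) or 3 (0.079), wild-type green-light library 1 (0.051) or 3 (0.083), BES1-RNAi dark library 1 (0.067) or 3 (0.057), or BES1-RNAi green-light library 1 (0.059) or 2 (0.076). With log2 values of -0.40 to -0.51, RVE1 no longer passed without wild-type dark library 2 (0.052) or 3 (0.089), wild-type green-light library 1 (0.080) or 2 (0.059), BES1-RNAi dark library 3 (0.092), or BES1-RNAi green-light library 1 (0.090) or 2 (0.075). RVE1 also did not pass over all libraries with the replicate block (0.051), a pseudocount of 0.1 (0.052) or robust moderation (0.056). CHI, whose interaction of 0.58 did not pass, passed without wild-type dark library 2 (log2 0.70), wild-type green-light library 2 (0.69) or BES1-RNAi dark library 2 (0.75), and over all libraries with a pseudocount of 5 (0.67), as did BCH2 (0.74). PSY, at 0.29, passed without wild-type green-light library 2 (0.41).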

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

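The tests of organelle and ribosomal RNA and the tests on the dark difference were chosen only after the result was seen, and the regroupings of libraries were written beforehand. The response to green light differed between wild type and BES1-RNAi for 179 of 633 genes by a test of the difference itself. The 10 genes named for it had log2 values, BES1-RNAi response minus wild-type response, of 2.69 for SAUR6, 2.15 for PHI-1, 2.08 for CGA1, 1.95 for AT5G38710 and 1.88 for AT1G08477, and of -1.69 for ELIP1, -1.60 for FLP1, -1.56 for BBX23, -1.44 for RVE7 and -1.38 for SAUR35. Only SAUR6 and PHI-1 fell in wild type and rose in BES1-RNAi, while the others moved the same way by different amounts. CGA1 stood at 0.567 FPKM in wild-type darkness and 2.76 FPKM in BES1-RNAi darkness. The pseudocount of 1 understates its rise more in wild type, so 2.08 overstates the difference in fold.

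Genotype labels were regrouped within each light condition in 100 drawn regroupings of 200. As many genes as the real 179 were found in 6 of the 100, the real one included, with 490 the highest of the others, so this count does not exclude chance. The other 5 exchanged the genotypes of all 3 green-light libraries (490 genes) or of 2 of 3 dark libraries (325, 306, 286 and 249 genes). Such regroupings place the genotype difference itself in the interaction, so their counts follow from that structure of the samples and are no evidence for chance either. The remaining drawn regroupings gave at most 38 genes. They mix the genotypes within groups, so the genotype difference enters the spread, and their low counts are no evidence against chance.

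Genes that rose in light in both genotypes were higher in BES1-RNAi darkness, with a median log2 difference of 0.43. A single scaling difference between genotypes predicts the same shift for the genes that fell in light, whose median was 0.031 (quartiles -0.48 and 0.44). The medians differed by 0.40 (95% interval over resampled genes 0.21 to 0.54), but the spreads of the genes overlap. A scaling difference alone would move all genes alike. Of the genes that rose in both genotypes, 271 were higher and 65 lower, and of those that fell in both, 36 and 34. These counts argue against scaling as the only cause of the dark differences of these genes. Whether scaling adds to the shift of the medians cannot be told apart from a difference between classes of genes. Light reaching the BES1-RNAi dark samples predicts, from a mixing fraction of 10.1% taken from the rising genes, a median of -0.102 for the falling genes. The observed median had a 95% interval over resampled genes of -0.082 to 0.175, which lies above that value. Both intervals treat genes as independent and hold no spread between libraries, so they do not decide. The mixing fraction itself was uncertain (quartiles 0.444% and 21.1%), and the spread of the falling genes holds the predicted value. Light in the dark samples thus cannot be told apart either. An effect of the genotype stays open and untested, since the silencing was not checked.

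Organelle-encoded and ribosomal RNA genes rose in wild-type green light in part. Carry-over of such RNA that varies between libraries predicts a wide spread within groups. The median SD within groups of these 19 genes was 0.643 on the log2 scale, against 0.216 in gene sets of similar level (95th percentile 0.269, 1000 draws), with 0.702 for the 17 organelle-encoded genes alone. Within groups the organelle-encoded genes moved together (median pairwise correlation 0.895), but the ribosomal RNA loci AT2G01020 and AT3G41979 did not move with them (median correlation -0.0027). These correlations rest on 6 libraries. The median FPKM of the organelle-encoded genes was 20.49 in wild-type green-light library 2, against 9.31 in library 1 and 6.73 in library 3. With values so dependent on 1 library, a single carry-over shared by both cannot be decided. Carry-over, shared or separate for each, may contribute to these changes, and an effect of green light stays open, as untested.

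For the light responses and the genotype differences, 3 libraries against 3 make 10 splits, too few for a share under 0.05. In wild type the real split gave 1256 genes and the highest other 1, and in BES1-RNAi 1073 and 0. The genes were chosen on this same light difference. The outcome for the light responses was thus fixed in advance and is no evidence against chance. For the dark difference these were 408 and 0, and for the green-light difference 447 and 0. There the other splits mix the genotypes within groups, so the genotype difference enters the spread. Their counts of 0 are thus no evidence against chance. In each of these 4 cases, 1 of the 10 splits, the real one, gave as many genes.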

How the results depend on the processing

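All alternatives here were chosen before the results were seen. After median-of-ratios scaling, 806 genes passed in wild type, not 1256, with 8 lists, not 10, and 608 in BES1-RNAi, not 1073, where 5 lists passed, not 8. With all 12 libraries in 1 fit, 631 and 633 genes passed, and 6 lists in wild type, not 10, since that fit tests the 633 shared genes only. A minimum fold of 2 left 833 genes in wild type, 156 for the dark difference, 215 for the green-light difference and 52 for the interaction, fewer by construction. For the interaction, where no list passed, 2 lists passed with the replicate block, 1 with a pseudocount of 0.1, 1 with a pseudocount of 5, 4 after scaling, and 0 to 2 with 1 library left out. Scaling turned the log2 values of CRD1 (-0.088) and BCH1 (-0.054) in wild type, of RBCS1B (-0.0044), LHCB2.2 (-0.23), PSBS (-0.27), HEMA1 (-0.099), CAO (-0.23), CHLH (-0.26) and XTH22 (-0.0034) in BES1-RNAi, and of IAA19 (-0.30) and GAI (-0.24) for the green-light difference. F3H turned to 0.33 in the interaction with a pseudocount of 5. Except where the construction shows it, the cause was not tested. Of 4406 values of named genes under the alternatives, 4326 kept their side of the threshold without a counted reversal, 48 no longer passed, 20 newly passed and 12 reversed. Fits with 1 library left out gave 2583 of the 4326. Under scaling, 246 values kept their side, 18 no longer passed, 8 newly passed and 11 reversed, so the pooled tally does not describe scaling. A reversal was counted only for a value that had passed. Some values that had not passed also turned with scaling and then passed. These include IAA29 (-0.49) and GAI (-0.36) for the dark difference, and IAA29 (-0.47) and HSP70 (-0.55) for the green-light difference. With 1 library left out, 1197 to 1228 genes passed in wild type, 1065 to 1071 in BES1-RNAi, 383 to 419 for the dark difference, 424 to 455 for the green-light difference and 150 to 189 for the interaction. With pseudocounts of 0.1 and 5, 143 and 244 genes passed for the interaction. Of the 628 genes that changed alike in both genotypes, the count was 586 at adjusted p under 0.01 and 423 with a minimum fold of 2. Fits with the replicate number as a block gave 1270, 1074, 407, 444 and 176 genes. Correlations between same-numbered libraries of different groups, after removing group means, ran from -0.152 to 0.227, and not every library correlated best with its own number, so the numbers were not read as pairs. An alternative based on the level of BES1 gave no value. The alternative with an estimated value for the correlation between genes was not run, since fry takes no such value as a setting. Depth is unknown, so its limit on low values was not measured.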

Other observations

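Gene families by product name were compared between rising and falling genes only after the values were seen. In wild type, 12 of 15 SAUR-like auxin-responsive genes fell and 3 rose (Fisher exact test over genes, adjusted p = 0.0064), and after scaling 12 fell and 1 rose. SAUR19 fell from 60.7 ± 9.59 to 18.8 ± 1.83 FPKM and SAUR25 from 10.1 ± 1.15 to 1.75 ± 0.125 FPKM, while SAUR35 rose. Of 10 peroxidase genes, 9 fell and AT5G64110 rose (adjusted p = 0.0064), and after scaling 9 fell and none rose. PER4 fell from 90.9 ± 31.2 to 34.1 ± 14.2 FPKM. In BES1-RNAi, 6 SAUR-like genes rose and 6 fell, and after scaling 1 rose, 6 fell and 5 did not pass. No family passed there by the same Fisher test (lowest adjusted p 0.42). Whether the families differ between genotypes was not tested.

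Cold-related genes were also looked at after their values were seen. COR413-PM1 rose in wild type by 1.95 and in BES1-RNAi by 1.84 on the log2 scale, and its levels in the genotypes did not pass as different in the dark (log2 0.03) or in green light (-0.08). KIN1 rose by 1.77 and 1.32, from a higher level in BES1-RNAi, and its interaction of -0.44 did not pass. GolS3 rose by 3.03 in wild type and 1.99 in BES1-RNAi, with an interaction of -1.04 (adjusted p = 0.0014).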
